A study of Sus scrofa with 8 samples.

How the data were processed

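Messenger RNA of the porcine endometrium, the inner lining of the uterus, was measured by RNA-seq in 8 gilts (young female pigs) on day 14. Per the labels' protocols, the German Landrace gilts had not reached puberty and received 750 IU of PMSG, a gonadotropin that starts follicle growth. Ovulation was set off with 500 IU of hCG 72 h later. The 4 gilts of the pregnant group received Pietrain semen 24 h after hCG and again at 36 h, and the 4 control gilts received semen supernatant of the same boar. Tissue of pregnant gilts came from reddened zones where embryos attach, and that of controls from similar places, both without the muscle layer. The comparison therefore holds pregnancy and the choice of those zones together. RNA of 3 places along 1 uterine horn was pooled per animal, so each library stands for 1 animal. RNA integrity numbers lay between 7.0 and 8.8. Libraries were made from poly(A) RNA (5 µg of total RNA, fragments of 200 ± 25 bp, 15 PCR cycles) with a kit that does not mark the strand.

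The authors deposited raw read counts per transcript for each library, and 2 annotation files with exon positions, per the file headers. The submitters' processing notes name CASAVA 1.6, TopHat 1.4, Cufflinks 1.3 and DESeq, and the genome build Sscrofa10.2. The counting tool and its settings are not given in the sources used here. The tables hold 24139 transcripts of a merged assembly, tied to 21064 Entrez genes, of which 1847 have more than 1 transcript. Of the transcripts, 641 were assembled from the reads and are not reference models. Isoforms have nearly equal counts. Among 1723 genes with several transcripts and a mean count of at least 10 in the highest, the lowest transcript had a median of 0.941 of the count of the highest, as when reads in shared exons are counted for each isoform. Totals therefore overstate the number of reads, and the highest transcript per gene held 75.4% of the summed counts. Isoforms of a gene are not independent in the tests. Total counts per library ran from 28035007 to 41016150.

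Gene symbols came from a RefSeq gene table of assembly Sscrofa11.1, used for names only. By Entrez ID 16270 genes matched, by transcript accession a further 103, and 4691 had no symbol. Transcripts with a symbol other than a LOC identifier numbered 16803 and held 76.2% of the counts. Coordinates span the Entrez gene in the deposited annotation on Sscrofa10.2, counted from 1, and counts are over exons. In that annotation 1151 genes share exonic bases with another gene, 926 of them with one on the opposite strand, and without strand their reads cannot be told apart. For 22 transcripts the gene ID differed between the deposited tables.

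The deposited counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with a minimum count of 10, robust quasi-likelihood fit and test, group as the only term). Benjamini-Hochberg adjustment ran over the 18783 transcripts tested, with an adjusted p under 0.05 as the threshold, and the filter left out 5356. SE of log2 changes are those implied by the F statistic. CPM are counts divided by the TMM-scaled library size and brought to a common total. A gene without reads in a group was given a fold against a floor of 3 counts over the group, and one with 1 to 3 counts a ratio with an exact 95% binomial interval. PCR reads are not independent molecules, so floors and intervals cover counting error only.

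Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the 41 lists with at least 5 tested members. The transcript with the highest mean count stood for each gene. A list of Y-linked genes had 2 matched members and 0 tested, with 0 reads in controls and 2 in pregnant animals. The spread between animals was compared by an exact permutation test over 35 splits, and named with unnamed transcripts by Fisher's exact test.

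The groups, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Named were the 8 largest rises and the 8 largest falls among transcripts that passed, with a symbol, an average log2 CPM of at least 1 and no overlap between groups. Also named were up to 4 members of each list with the smallest p, of which the text leaves some out, 15 fixed genes whatever their result, and the 4 unnamed transcripts with the smallest p. Of the fixed genes, IL1RAP matched no tested symbol and is not analysed here. Some genes that the rule takes in are not reported here. CCL28, C7, MRC1, IL1A, IL11RA, IL18R1 and KCNMB1 lie outside the rule and were chosen after their values were seen, as list members that differed from the rest of their list or completed a small count.

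The tests were run on simulated data for the comparison of pregnant with control. Among 18618 simulated transcripts, edgeR found 3.64% of 55 changes of 1.5-fold, 54.9% of 71 of 2-fold and 92.8% of 69 of 4-fold, and 7 of its 112 calls were false. Far fewer transcripts were changed there than passed in the real data (4009 of 18783), which makes the adjusted threshold stricter. These shares therefore do not give the share of real changes found. Camera called 5 of 5 changed and 0 of 20 unchanged lists among 18783 transcripts simulated independently of each other, which real list members are not. Libraries of a group differed by more than sampling noise in each pair, with a median chi-square per transcript of 4.61 to 15.9, against 0.455 for noise alone. Alternatives were other scalings and filters, stricter thresholds, DESeq2 1.42.0, limma voom, a non-robust fit, a replicate block, leaving out each library, thinning to the smallest library, counts summed per gene, fry, and camera with an estimated correlation or without shared members. Using 1 transcript per gene was added after seeing the data.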

Results

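The endometrium of 4 pregnant and 4 non-pregnant gilts was compared on day 14 after insemination, to find genes whose messenger RNA differed in early pregnancy. Each library was made from 1 animal. The total counts were 30547312, 31084620, 28035007 and 32639743 in control replicates 1 to 4 and 29009827, 41016150, 32853822 and 32763612 in pregnant replicates 1 to 4. A total of 18783 transcripts of 15913 genes could be tested. Values in CPM, counts scaled to a common library size, are means ± SD with n = 4 per group, and log2 changes are pregnant over control ± SE. For the genes given below as changed, the 4 pregnant values lay on one side of the 4 control values, except for FGF7, RBP4, GPER1, DPT, CCL28, MRC1, IL11RA, IL18R1 and LYVE1.

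In pregnant endometrium 29 of 34 tested interferon-stimulated genes and 25 of 26 antigen processing and presentation genes rose. The interferon-induced chemokine CXCL10 rose from 6.09 ± 2.92 to 940.1 ± 446 CPM, and the guanylate-binding protein GBP1 from 32.4 ± 10.9 to 1501 ± 418 CPM. The calcium channel TRPV6 rose from 292 ± 231 to 3562 ± 401 CPM. AGR2, a protein disulfide isomerase of secretory cells, fell from 596 ± 58.9 to 8.43 ± 3.96 CPM, and keratin 8 (KRT8) from 1257 ± 252 to 294 ± 53.01 CPM.

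By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4009 of the 18783 transcripts (21.3%) passed an adjusted p of 0.05, with 2111 higher and 1898 lower in pregnant animals. They belonged to 3464 genes. Changes of at least 2-fold were found for 1324 higher and 785 lower transcripts, and of at least 8-fold for 187 and 97. The groups did not overlap for 4894 transcripts (26.1%), where chance gives 2.86%. The number of lower transcripts was 1265 without pregnant replicate 2.

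The first principal component of the 500 most variable transcripts held 76.9% of their variance and separated the groups. Spearman correlations across transcripts were 0.967 to 0.986 within groups and 0.916 to 0.957 between them. Control replicate 4 scored −27.81 on this component, the other controls −46.07 to −42.32 and the pregnant libraries 35.48 to 42.19. Without control replicate 4, 4127 transcripts passed and camera called 13 gene lists. The mean distance between animals was 0.668 log2 units in controls and 0.567 in pregnant animals. The difference of −0.101 did not pass (two-sided exact permutation test over 35 splits, p = 0.143). The groups were not centred first, and animals of different groups lay 1.021 log2 units apart on average. The other splits therefore hold the group difference too, and this p does not measure spread alone.

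**Figure D1:**
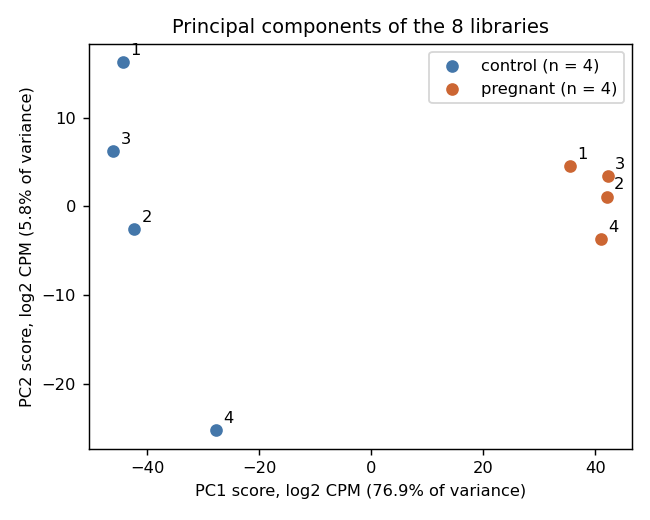
Scores of the 8 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis and the replicate number beside each point. The 4 control libraries lie at negative PC1 scores and the 4 pregnant libraries at positive ones, with control replicate 4 at −27.81.

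The largest rises were in genes with few reads in control endometrium. NPY, which encodes neuropeptide Y, had 0 reads in controls and 4452 in pregnant animals, at least 1466-fold higher against a floor of 3 counts over the group (Entrez gene 397304, chromosome 18, 52929673 to 52937701). CDSN, corneodesmosin of skin cell junctions, had 2 reads in controls, both in control replicate 1, so that controls had 0 reads without that library, and 12792 in pregnant animals, a ratio of 6316 with an exact 95% counting interval of 1748 to 52160 (Entrez gene 100144482, chromosome 7, 27309378 to 27311920). The calcium-binding protein gene S100A9 rose by 9.40 ± 0.55 (edgeR adjusted p = 9.41e-06; Entrez gene 100127489, chromosome 4, 105063476 to 105066297). IDO1, whose product degrades tryptophan, rose by 8.34 ± 0.49 (Entrez gene 100519877, chromosome 17, 10913717 to 10928812) and the signal protein gene WNT7B by 7.71 ± 0.70 (Entrez gene 100626947, chromosome 5, 657228 to 707040). PCK1, an enzyme of glucose synthesis, rose by 7.67 ± 0.53 (Entrez gene 100144531, chromosome 17, 65094782 to 65100750) and the acute-phase protein gene SAA3 by 7.46 ± 0.34 (Entrez gene 733603, chromosome 2, 44079074 to 44082797). The log2 change of WNT7B was 9.19 without control replicate 1. SAA and S100A genes belong to families of similar sequence, so the share of reads of a single member is uncertain.

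The largest falls included the water channel gene AQP5, from 14.4 ± 3.603 to 0.04601 ± 0.0316 CPM (log2 change −8.16 ± 0.40, edgeR adjusted p = 1.64e-06; Entrez gene 100126278, chromosome 5, 16079773 to 16082854). AGR2 fell in both of its transcripts (−6.15 ± 0.34 and −6.14 ± 0.33; Entrez gene 100514482, chromosome 9, 94843447 to 94855301). The log2 change was −6.14 ± 0.53 for the collagenase MMP8 (Entrez gene 100523811, chromosome 9, 37332087 to 37343612), −5.99 ± 0.63 for the growth factor FGF18 (Entrez gene 100525013, chromosome 16, 56921624 to 56956532), −5.87 ± 1.11 for the matrix protein OPTC (Entrez gene 397071, chromosome 9, 70505086 to 70514590) and −5.80 ± 0.59 for the small GTPase RAB26 (Entrez gene 100739113, chromosome 3, 42470477 to 42476011). The log2 change was −7.59 without pregnant replicate 2 for MMP8, −6.76 without pregnant replicate 4 for FGF18, and −5.22 without control replicate 2 and −6.91 without pregnant replicate 4 for OPTC. The RAB26 model shares exonic bases with another gene, so its value is uncertain. REG3G, an antimicrobial lectin, had a log2 change of −7.11 ± 1.5 with an edgeR adjusted p = 0.00907, but it did not pass with limma voom (adjusted p = 0.12; range over the alternatives 8.81e-06 to 0.12), and its log2 change was −8.03 without pregnant replicate 1.

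**Figure D2:**
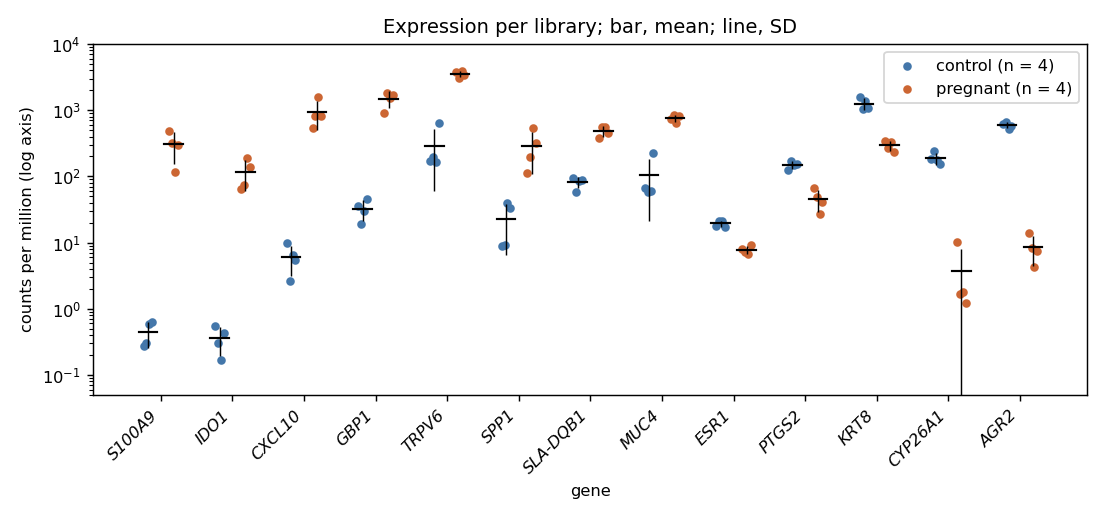
CPM on a log axis of 13 genes in each library, with 4 control and 4 pregnant points per gene, a bar at the mean and a line of 1 SD. The groups do not overlap for these 13 genes, and the lower SD line of CYP26A1 in pregnant animals (3.71 ± 4.28 CPM) runs below the axis.

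The interferon-stimulated genes that passed were higher in pregnant endometrium. Of 34 tested members 29 rose and 5 did not pass, and 30 rose when adjusted over the list alone (camera adjusted p = 4.32e-19, adjusted p = 0.378 with an estimated correlation). GBP1 rose by 5.53 ± 0.33, its relative GBP2 by 4.96 ± 0.28 and the transcription factor gene IRF1 by 3.29 ± 0.19, with edgeR adjusted p = 5.03e-06, 3.63e-06 and 4.25e-06. Of 26 antigen processing and presentation genes 25 rose and 1 did not pass, with 25 also adjusted over the list alone (camera adjusted p = 4.32e-19, adjusted p = 0.378 with an estimated correlation). The peptide transporter gene TAP1 rose from 103 ± 10.15 to 707 ± 194 CPM, the class II gene SLA-DQB1 from 82.2 ± 16 to 486 ± 89.3 CPM, and the protease gene CTSS by 2.37 ± 0.18. SLA and GBP genes have close relatives, so the reads of a single member are uncertain. In the same animals 11 of 12 T cell and 12 of 15 macrophage and dendritic cell markers rose.

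Of 32 chemokine and receptor genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with camera adjusted p = 2.58e-07, adjusted p = 0.395 with an estimated correlation. CXCL9, CXCL10 and CXCL11, ligands of a receptor on activated T cells, rose by 7.39 ± 0.46, 7.27 ± 0.51 and 5.98 ± 0.62, and CX3CL1 by 1.76 ± 0.21. The member that fell, CCL28 (−2.76 ± 0.79), did not pass without control replicate 1, 2 or 3 or pregnant replicate 2 or 4 (edgeR adjusted p = 0.0598 to 0.0893) or without the filter (0.058; range over the alternatives 0.00965 to 0.0893). Of 31 interleukin and cytokine genes 16 rose and 3 fell (18 and 3 adjusted over the list alone), with camera adjusted p = 5.38e-05, adjusted p = 0.378 with an estimated correlation. IL15, which supports natural killer cells, rose by 2.69 ± 0.34, its receptor chain IL15RA by 3.45 ± 0.25, the decoy receptor gene IL1R2 by 4.44 ± 0.50 and the signalling inhibitor gene SOCS1 by 2.41 ± 0.34. The 3 that fell were IL1A (−2.06 ± 0.30), IL11RA (−0.92 ± 0.22) and IL18R1 (−1.49 ± 0.43), the last of which did not pass without control replicate 2 or 3 or any 1 pregnant replicate (edgeR adjusted p = 0.0571 to 0.0986) or with limma voom (0.0796; range over the alternatives 0.00507 to 0.0986). The log2 change of IL1R2 was 5.43 without control replicate 4.

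Of 25 complement genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), with camera adjusted p = 1.84e-04, adjusted p = 0.395 with an estimated correlation. C2 rose by 2.94 ± 0.30 and CFB by 1.96 ± 0.27, and C7 fell (−1.93 ± 0.47; −1.25 without control replicate 4). Of 26 immediate early genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 0.00152, adjusted p = 0.411 with an estimated correlation. FOSL1 rose by 2.80 ± 0.38 and the phosphatase gene DUSP1 by 1.77 ± 0.30, and CTGF fell (−1.49 ± 0.19).

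Most tested markers of T cells, cytotoxic cells and macrophages rose in pregnant endometrium. Of 12 T cell markers 11 rose and 0 fell (12 and 0 adjusted over the list alone), with camera adjusted p = 1.41e-07, adjusted p = 0.378 with an estimated correlation. Of 12 natural killer and cytotoxic markers 11 rose and 0 fell (12 and 0 adjusted over the list alone), with camera adjusted p = 1.41e-07, adjusted p = 0.378 with an estimated correlation. CD2 rose from 4.27 ± 1.87 to 40.9 ± 21.4 CPM, CD3D of the T cell receptor complex from 1.77 ± 0.597 to 5.899 ± 0.901 CPM, and the cytotoxic protein genes GNLY and GZMA from 9.28 ± 2.39 to 51.2 ± 16.2 CPM and from 0.241 ± 0.0357 to 1.98 ± 0.618 CPM. Of 15 macrophage and dendritic cell markers 12 rose and 1 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 1.48e-06, adjusted p = 0.395 with an estimated correlation. AIF1 rose by 3.20 ± 0.26 and the complement gene C1QC by 1.59 ± 0.23, and the mannose receptor gene MRC1 fell (−0.77 ± 0.22). MRC1 did not pass without control replicate 2 or 4 or pregnant replicate 1, 3 or 4 (edgeR adjusted p = 0.0649 to 0.0841; range over the alternatives 0.0095 to 0.0841). Of 9 B and plasma cell markers 4 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0537). Of 9 neutrophil markers 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.166), with S100A9, S100A12 (5.06 ± 0.65) and S100A8 (4.38 ± 0.59) among those higher, and MMP8 lower. The log2 change was 6.48 without control replicate 4 for S100A12 and 4.98 without control replicate 3 for S100A8. Of 6 mast cell and eosinophil markers 0 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.7), with HDC, the enzyme that makes histamine, at −2.99 ± 0.45. The median log2 change over these 6 markers was 0.425 and the mean −0.004, so HDC does not stand for the list.

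Smooth muscle was the list called lower. Of its 11 members 0 rose and 5 fell (0 and 6 adjusted over the list alone), with camera adjusted p = 0.0117, adjusted p = 0.49 with an estimated correlation. The genes were ACTG2 (−1.59 ± 0.27), CNN1 (−1.37 ± 0.25), ACTA2 (−0.82 ± 0.18), SYNM (−0.66 ± 0.14) and KCNMB1 (−0.99 ± 0.25). KCNMB1 did not pass without pregnant replicate 2 or 4 (edgeR adjusted p = 0.0542 and 0.051; range over the alternatives 0.00282 to 0.0542). Of 15 epithelial markers 1 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.0762). The keratin genes KRT8 (−2.10 ± 0.19), KRT18 (−1.58 ± 0.18) and KRT19 (−1.83 ± 0.30) fell, and the tight junction gene CLDN4 rose (1.06 ± 0.20). Of 15 stromal fibroblast markers 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.491), among them THY1 (3.16 ± 0.25) and DPT (−1.34 ± 0.31). Of 14 vascular endothelial markers 2 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.0762), CLEC14A (0.75 ± 0.12) and KDR (0.77 ± 0.17). Of 5 lymphatic markers 0 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.185), PDPN (−1.54 ± 0.38) and LYVE1 (−1.69 ± 0.45). LYVE1 did not pass without control replicate 4 or pregnant replicate 1, 3 or 4 (edgeR adjusted p = 0.0529 to 0.0706; range over the alternatives 0.00123 to 0.0706).

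Of 14 ciliated-cell markers and 5 erythrocyte markers, edgeR passed 0 and 0, also when adjusted over the list alone. At an unadjusted p under 0.05 there were 2 and 1, DESeq2 passed 1 and 0, and limma voom 0 and 0. Camera adjusted p was 0.423 for both lists. Of 15 genes of the conceptus (the embryo with its membranes) and steroid synthesis 5 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.525). Endometrium expresses some of these too, and the list included PLAC8 (4.66 ± 0.35) and KRT8.

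**Figure D3:**
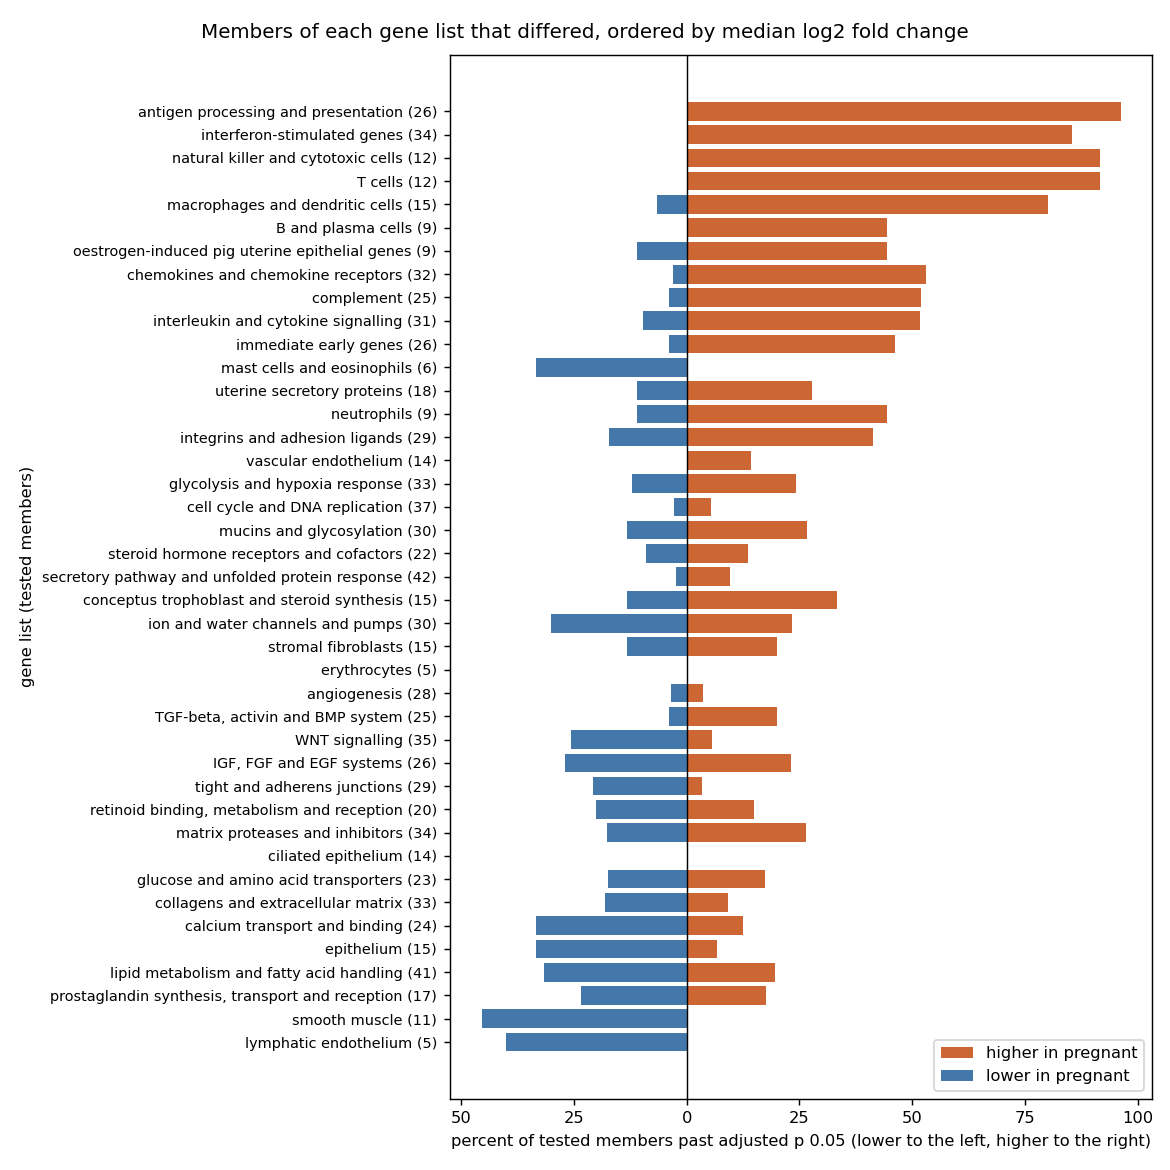
Percent of the tested members of 41 gene lists with an edgeR adjusted p under 0.05, higher in pregnant animals to the right and lower to the left, with the number tested in brackets. Antigen processing and presentation reached 96.2% higher and interferon-stimulated genes 85.3%.

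Camera called 10 of the 41 lists, 9 higher and 1 lower. With an estimated correlation it called 0, with 4 lists at an unadjusted p under 0.05, and fry called 23. Of the 35 splits of the 8 libraries into 4 and 4, 17 gave at least 10 called lists, the highest other split 15. The member counts given for each list come from the edgeR test of single transcripts, which called at most 4 transcripts in any other split. Every other split mixes the groups, which adds to the spread within each side and lowers these calls. That number therefore does not by itself exclude chance for the member counts.

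Genes of steroid hormone action changed in both directions. Of 22 receptors and cofactors 3 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.423). This is near the 21.3% that passed among all transcripts tested. The oestrogen receptor gene ESR1 fell from 19.4 ± 2.03 to 7.75 ± 1.05 CPM (edgeR adjusted p = 1.94e-04), and GREB1, an oestrogen-responsive gene, rose by 3.64 ± 0.53 (4.47 without control replicate 2). The membrane oestrogen receptor gene GPER1 fell (−1.81 ± 0.42, edgeR adjusted p = 0.0144), but did not pass without control replicate 1 (0.0507; range over the alternatives 2.92e-05 to 0.0824). The progesterone receptor gene PGR was at 6.21 ± 1.66 in controls and 6.85 ± 0.769 CPM in pregnant animals (edgeR adjusted p = 0.681).

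Of 9 genes known to be induced by oestrogen in pig uterine epithelium 4 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.0708). SPP1, the adhesion protein osteopontin, rose from 22.7 ± 16.1 to 291 ± 182 CPM (edgeR adjusted p = 0.00393). TNFSF10 (3.57 ± 0.44), AKR1B1 (1.57 ± 0.24) and IRF2 (0.99 ± 0.18) also rose, and FGF7 fell (−1.53 ± 0.35). LPAR3 was at 10.4 ± 6.07 and 12.1 ± 3.05 CPM in controls and pregnant animals (edgeR adjusted p = 0.732), with a log2 difference of 0.22 that was −0.03 without control replicate 4. STC1 was at 74.5 ± 73.5 and 236 ± 142 CPM (edgeR adjusted p = 0.0955). Control replicate 4 stood at 184 CPM, and STC1 passed without that library (log2 change 2.63, adjusted p = 0.00221) and with limma voom (0.0324; range over the alternatives 0.00221 to 0.235).

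Of 17 prostaglandin genes 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.613). The cyclooxygenase gene PTGS1 rose by 2.00 ± 0.18, and the other cyclooxygenase gene, PTGS2, fell from 149.8 ± 20.4 to 45.8 ± 16.5 CPM. The phospholipase gene PLA2G4A (−1.06 ± 0.15) and the synthase gene PTGES (−1.16 ± 0.26) also fell. Of 18 uterine secretory protein genes 5 rose and 2 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.0847), with the protease gene CTSC at 1.87 ± 0.28. ACP5, which encodes uteroferrin, was at 269 ± 57.5 and 366 ± 72.6 CPM in controls and pregnant animals (edgeR adjusted p = 0.127), and passed without pregnant replicate 1 (0.044; range over the alternatives 0.044 to 0.277). The retinol carrier gene RBP4 rose from 3518 ± 1066 to 6256 ± 1026 CPM (edgeR adjusted p = 0.023). It did not pass without control replicate 1, 2 or 3 or pregnant replicate 1, 2 or 3 (adjusted p = 0.0505 to 0.0635; range over the alternatives 0.00237 to 0.0635). Of 20 retinoid genes 3 rose and 4 fell (4 and 6 adjusted over the list alone, camera adjusted p = 0.423). The retinoic acid hydroxylase gene CYP26A1 fell from 188 ± 37.9 to 3.71 ± 4.28 CPM (log2 change −5.69 ± 0.70; −6.90 without pregnant replicate 1) and the binding protein gene CRABP1 fell (−3.15 ± 0.61), and the retinol transporter gene STRA6 rose by 1.07 ± 0.14.

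Of 24 calcium genes 3 rose and 8 fell (6 and 8 adjusted over the list alone, camera adjusted p = 0.387). TRPV6, whose model overlaps another gene, rose by 3.61 ± 0.46 (4.33 without control replicate 4). PTHLH rose by 4.22 ± 0.24, and S100A2 (−2.44 ± 0.17) and ANXA2 (−0.85 ± 0.14) fell. Of 30 ion and water channel genes 7 rose and 9 fell (7 and 12 adjusted over the list alone, camera adjusted p = 0.423). The water channel gene AQP3 fell (−2.15 ± 0.29), and the anion exchanger gene SLC26A4 rose by 4.65 ± 0.45. Of 41 lipid genes 8 rose and 13 fell (8 and 14 adjusted over the list alone, camera adjusted p = 0.055), with ACSL1 (2.00 ± 0.19) higher and the desaturase genes SCD (−1.33 ± 0.15) and FADS1 (−1.16 ± 0.13) lower. The SCD model overlaps another gene. Of 23 glucose and amino acid transporters 4 rose and 4 fell (4 and 9 adjusted over the list alone, camera adjusted p = 0.166), with SLC2A8 (−3.17 ± 0.29) and SLC2A3 (−2.04 ± 0.39) lower. Of 33 glycolysis and hypoxia genes 8 rose and 4 fell (9 and 6 adjusted over the list alone, camera adjusted p = 0.227), with PFKFB3 at 1.91 ± 0.22.

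Adhesion and mucin genes changed in both directions. Of 29 integrin and adhesion genes 12 rose and 5 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.143), with ITGB4 lower (−1.56 ± 0.19). Of 30 mucin and glycosylation genes 8 rose and 4 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.166). MUC4 rose from 104 ± 82.7 to 761 ± 89.8 CPM (log2 change 2.88 ± 0.45; 3.61 without control replicate 4), and MUC1 was at 33.05 ± 9.23 and 39.3 ± 11.1 CPM in controls and pregnant animals (edgeR adjusted p = 0.49). Of 29 junction genes 1 rose and 6 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.215). Of 33 matrix genes 3 rose and 6 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.172), with the laminin gene LAMB3 at 4.20 ± 0.59 (5.00 without control replicate 4). Of 34 matrix proteases and inhibitors 9 rose and 6 fell (10 and 10 adjusted over the list alone, camera adjusted p = 0.726).

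Among signalling lists, of 26 insulin-like, fibroblast and epidermal growth factor genes 6 rose and 7 fell (7 and 8 adjusted over the list alone, camera adjusted p = 0.927), with FGF9 at 2.42 ± 0.28. Of 25 genes of the transforming growth factor beta system 5 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.371), with TGFB2 at 1.35 ± 0.17. Of 35 WNT genes 2 rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.168), with WNT7B higher and WNT2 lower (−1.36 ± 0.22). Of 28 angiogenesis genes 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.967), KDR higher and DLL4 lower (−1.45 ± 0.12). Of 37 cell cycle genes 2 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.342), and of 42 secretory pathway genes 4 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.454). At an unadjusted p under 0.05 edgeR had 5 cell cycle and 11 secretory pathway genes, while DESeq2 passed 4 and 10 and limma voom 3 and 8 by adjusted p. Median, mean and camera direction differed in sign for the lists of calcium, ion channels, proteases, growth factors, the transforming growth factor beta system, angiogenesis, erythrocytes, and mast cells and eosinophils.

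Transcripts without a gene name passed less often than named ones. Of 4300 unnamed transcripts 822 (19.1%) passed, against 3187 of 14483 named ones (22%), an odds ratio of 0.838 with a 95% interval of 0.768 to 0.913 (two-sided Fisher's exact test, p = 4.69e-05). This comparison is descriptive, because transcripts are not independent. Of 610 transcripts assembled from the reads 124 passed. The unnamed transcripts with the smallest p were TCONS_00015566 (log2 change 6.39 ± 0.28; chromosome 4, 139453256 to 139485845), TCONS_00017974 (3.45 ± 0.15; chromosome 6, 155973388 to 155984615), TCONS_00019010 (3.33 ± 0.15; chromosome 6, 156037475 to 156059054) and LOC100519934. The last rose from 1.99 ± 1.19 to 1307 ± 203 CPM (chromosome 1, 82268686 to 82273305).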

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

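The tests of tissue composition, conceptus RNA and neutrophils and the splits for single lists were chosen after the results were seen, while the splits for the numbers of transcripts and lists were planned. Of the 35 splits of the 8 libraries into 4 and 4, 1 called as many transcripts as the real split, which was the real one itself (4009 transcripts, highest other 4). A share of 1 of 35 is the smallest that these splits can give, before adjustment over the numbers of transcripts and lists. Every other split mixes the groups, so a large group difference adds to the spread within each side and lowers the calls. The count argues for a difference between the groups but does not by itself exclude chance. For the number of lists, 17 of the 35 splits called at least as many as the real 10 (highest other 15). Many of these put 3 animals of a group with 1 of the other, and so keep part of the group difference. The split with 15 lists put 2 controls with 2 pregnant animals, so camera can call as many lists without that difference. The number of lists therefore does not decide on chance, which stays open. In the exact enumeration of the splits for single lists, 1 of 35 gave a camera p as small for interferon-stimulated genes (p = 1.39e-20, smallest other 2.38e-16), for antigen processing and presentation (2.11e-20 and 4.88e-18) and for interleukin and cytokine signalling (9.19e-06 and 3.02e-05). The 35 splits are too few for a share under 0.05 once adjusted over the 10 lists, which were picked because they were called. In the same exact enumeration chance cannot be excluded for natural killer and cytotoxic cells and for macrophages, with 2 of 35 splits each (7.63e-09 and 4.55e-09), for T cells, chemokines and complement, with 4 each (2.84e-12, 1.39e-11 and 1.04e-06), for immediate early genes with 5 (1.10e-09) or for smooth muscle with 7 (2.74e-05).

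A single library stood far from the other 3 of its group in 24 of 222 groups of values examined. Chance gives about 1 in 20, or 11.1, for independent and normally distributed values. CPM were not transformed and the genes share the same animals, so 24 against 11.1 does not show an excess. The number in brackets is the gap to the nearest other library over the range of the group. For CDSN, control replicate 1 was highest at 0.0678 CPM, the others at 0 (1). For MMP8, pregnant replicate 2 was highest at 0.418 CPM, the others at 0.0354 to 0.0662 (0.92). For STC1, control replicate 4 was highest at 184 CPM, the others at 29.9 to 49.6 (0.872). For AKR1B1, control replicate 1 was highest at 42.6 CPM, the others at 27.2 to 29.2 (0.871) and pregnant replicate 2 was highest at 147 CPM, the others at 72.7 to 84.1 (0.846). For GBP2, pregnant replicate 1 was lowest at 174 CPM, the others at 327 to 359 (0.83). For IRF1, pregnant replicate 1 was lowest at 318 CPM, the others at 505 to 538 (0.849). For CX3CL1, pregnant replicate 2 was highest at 35.5 CPM, the others at 25.8 to 27.3 (0.84). For IL1R2, control replicate 4 was highest at 0.945 CPM, the others at 0.136 to 0.266 (0.84) and pregnant replicate 1 was highest at 11.2 CPM, the others at 7.51 to 7.92 (0.888). For SOCS1, pregnant replicate 4 was lowest at 84.1 CPM, the others at 126 to 133 (0.852). For GNLY, control replicate 2 was lowest at 5.72 CPM, the others at 10.17 to 10.8 (0.871). For CD3D, control replicate 4 was highest at 2.66 CPM, the others at 1.43 to 1.53 (0.92). For FOSL1, pregnant replicate 1 was lowest at 2.05 CPM, the others at 5.16 to 5.34 (0.946). For CTGF, pregnant replicate 3 was highest at 1037 CPM, the others at 679.6 to 740.2 (0.83). For TRPV6, control replicate 4 was highest at 638 CPM, the others at 166 to 196 (0.936). For CYP26A1, pregnant replicate 1 was highest at 10.1 CPM, the others at 1.22 to 1.82 (0.933). For STRA6, control replicate 2 was highest at 203 CPM, the others at 147 to 154 (0.886). For GREB1, control replicate 2 was highest at 4.91 CPM, the others at 0.863 to 1.49 (0.845). For FGF9, pregnant replicate 4 was lowest at 13.97 CPM, the others at 15.5 to 15.7 (0.877). For MUC4, control replicate 4 was highest at 227 CPM, the others at 58.04 to 67.9 (0.942). For SCD, pregnant replicate 2 was highest at 25.7 CPM, the others at 20.9 to 21.5 (0.874). For MRC1, pregnant replicate 2 was highest at 10.24 CPM, the others at 6.86 to 7.33 (0.863). For LYVE1, pregnant replicate 2 was highest at 4.23 CPM, the others at 1.66 to 1.83 (0.935).

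Markers of T cells, cytotoxic cells and macrophages were higher in pregnant endometrium, with a lower quartile of 1.15 and a median of 1.49 on the log2 scale over 39 markers. A lower share of epithelial RNA would raise markers of all other cell types alike, but the upper quartile of 45 stromal, smooth muscle and endothelial markers was 0.256. More blood in the tissue is argued against only weakly by 5 erythrocyte markers, with a median of 0.0214 and quartiles of −0.252 and 0.117. The quartiles are over markers and do not measure the spread between animals. The log2 change ± SE was −0.46 ± 0.20 for SLC4A1, −0.25 ± 0.46 for ALAS2, 0.12 ± 0.55 for HBZ and 0.41 ± 1.05 for HBE1. HBB, the remaining marker of the 5, gave the median itself. Its values per library, picked for display after they were seen, ran from 210 to 504 CPM in control and from 157 to 789 CPM in pregnant animals. More immune cells and more transcript per immune cell both stay open and were not tested, as does the choice of reddened zones in pregnant animals only, which the design does not separate from pregnancy.

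The 8 largest rises were in genes nearly without reads in control endometrium, and RNA of the conceptuses could be a source. The fixed conceptus genes with a control mean under 1 CPM, 15 genes, summed to 3.67 ± 0.294 CPM in pregnant and 2.07 ± 0.375 CPM in control animals (SD, n = 4). The most abundant in pregnant animals were PAG1 (0.974 CPM), whose symbol may stand for another gene, HSD3B1 (0.603) and IFN-DELTA-1 (0.556). In control animals, without conceptuses, PAG1 was at 0.3135, HSD3B1 at 0.612 and IFN-DELTA-1 at 0.441 CPM. The lowest of the 8 genes reached 33.6 CPM, but each of the 15 genes lay under 1 CPM and their levels in conceptuses were not measured, so conceptus RNA stays open. Expression by the endometrium itself in pregnancy also stays open and was not tested.

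S100A8, S100A9 and S100A12, abundant in neutrophils, rose by 4.38 ± 0.59, 9.40 ± 0.55 and 5.06 ± 0.65. More neutrophils are argued against by the 6 other tested markers, with an upper quartile of 0.263 and a median of −0.205, although 1 of the 6 rose. Over the pregnant libraries S100A12 ran from 3.04% to 15.1% of S100A9 and S100A8 from 0.295% to 1.26%. A fixed share of S100A9 reads counted for them would give similar percentages in each library. The values argue against such reads as the only source of S100A12 or S100A8. A part of their reads coming from S100A9 stays open, since the sequences were not compared. Expression in other cells, such as epithelium, is a hypothesis that stays open and was not tested.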

How the results depend on the processing

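The alternative with 1 transcript per gene was chosen after seeing the data. The number of transcripts called was 3850 to 4982 over the other scalings, filters, tools, thinning and the replicate block, 3463 with counts summed per gene and 3436 with 1 transcript per gene. An adjusted p under 0.01 left 2137 (1246 higher, 891 lower), and a minimum of 2-fold 2109 (1324 and 785), both by construction. Leaving out 1 library gave 2864 to 4127, with 1265 lower without pregnant replicate 2 and 2017 without control replicate 4, and the cause was not tested. Replicate numbers did not pair the animals (correlations of deviations 0.186, −0.0932, −0.0318 and 0.0854 for replicates 1 to 4). With the replicate block 3883 transcripts were called, 3520 of them among the 4009. Camera with an estimated correlation called 0 lists and fry 23, as they assume other correlations or ask another question. All 10 lists remained called with RLE scaling, the stricter filter, the block, without shared members and without any 1 library (10 to 14 lists). Of the lists not called, the direction reversed for angiogenesis with fry (adjusted p = 0.749) and without shared members (0.526) and without control replicate 2 or 3 or pregnant replicate 1 or 2 (0.543 to 0.991 without 1 library), for the growth factor systems without shared members (0.818) and without pregnant replicate 3 (0.833 to 0.992 without 1 library), and for mast cells and eosinophils without shared members (0.791) and without control replicate 4 (0.525 to 0.857), and the cause was not tested.

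Of 109 named genes, 97 kept their direction and side of the threshold in every alternative that gave a value. Of 2069 values 37 lost the threshold, 3 gained it and 1 reversed, LPAR3 at −0.0261 without control replicate 4 (0.529 without control replicate 3), and the cause was not tested. The block ended the calls of RBP4 (adjusted p = 0.051), GPER1 (0.0824), DPT (0.0612), CCL28 (0.0727) and IL18R1 (0.0902), and of no other named gene. The difference in spread between animals within groups was −0.0813 for the 500 highest transcripts, −0.0993 with RLE and −0.00734 as 1 minus the Spearman correlation. Without 1 library it was −0.135 to −0.0512, and it did not pass in any alternative. These tests did not centre the groups first either. The odds ratio of features without a gene name was 0.864 with the stricter filter, 0.799 with LOC identifiers as named and 0.808 to 0.903 without 1 library, and passed in each. Depth limits genes such as NPY and CDSN, with 0 and 2 control reads.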

Other observations

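The genes in this part were chosen after their values were seen. Some conceptus genes had more reads in pregnant than in control libraries, summed over 4 each. CYP19A2, a conceptus aromatase gene, had 0 in controls and 14 in pregnant animals, the interleukin gene IL1B2 2 and 14, IFNG 4 and 26, HAND1 4 and 16, and POU5F1 0 and 10. The steroid synthesis genes CYP17A1 (11 and 7), STAR (52 and 55) and HSD3B1 (76 and 77) had similar numbers. Immune cells express IFNG too. No test was made on these counts.

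Haemoglobin beta (HBB) stood at 456, 210, 504 and 269 CPM in control replicates 1 to 4 and at 157, 789, 263 and 251 CPM in pregnant replicates 1 to 4.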
